A study of Homo sapiens with 12 samples.

How the data were processed

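Messenger RNA levels were measured on 12 Affymetrix Human Gene 1.0 ST arrays of SK-mel147 cells, an established human melanoma line. The cells carried lentiviral short hairpin RNAs. The arrays fall into 6 hairpins with 2 arrays each: sh_37 and sh_38 against H2AZ2 (protein H2A.Z.2), sh_83 and sh_84 against H2AZ1 (protein H2A.Z.1), and the control hairpins scrambled and luciferase. Each target therefore has 4 arrays. The titles speak of siRNA and the treatment protocol of lentiviral hairpins; the wording of the protocol is used here. For replicate 2 of sh_84 the title and the RNAi characteristic name different hairpins, and the title was followed. Nothing in the labels says that replicates came from separate cultures or infections, so p-values measure the spread between these arrays, which may be technical. Their number limits the precision.

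The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes; its version, the software and any filter are not given in the sources used here. Column medians differed little between arrays, and no further normalization was applied in the main setting. Of the 33297 probe sets, 19460 had 1 gene symbol in the platform annotation, 1754 had several and 12083 were not listed there. Genes were named only from probe sets with 1 symbol, and 19429 of these matched the reference gene table by Entrez ID. Where a gene had several probe sets (769 genes), the brightest by mean over all arrays was kept, which gave 18417 genes. No scan dates or array background values were analysed here, so no scan batch was tested and signal over background is unknown.

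All tests used limma 3.58.1 in R 4.3.3. The main fit held 3 targets with the hairpin as a random block (duplicateCorrelation, consensus correlation 0.157), moderated statistics (eBayes), and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. The block uses the same correlation for every gene. Where the hairpins of a target differ more than that, as for TAGLN, the SE and adjusted p are too small. Tests of single hairpins came from a fit with the 6 hairpins as groups of 2 arrays, which takes no account of spread between hairpins of a target. Gene lists, 28 in all with 621 of 677 entries measured, were tested with cameraPR at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Each list was tested again with a correlation estimated from its residuals (6 residual degrees of freedom) and with fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. No list passed with the estimated correlation in any of the 3 main comparisons. List scores per array were compared by an exact two-sided permutation test of 4 against 4 arrays, whose smallest p is 0.0286.

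The lists, tests, naming rule and most alternatives were fixed before the data were examined. Named genes are the targeted genes, the 8 largest rises and 8 largest falls among called genes whose 4 arrays lay wholly above or below the 4 control arrays (5 each way for H2AZ2 against H2AZ1), and up to 3 members in the direction of each called list, for at most 8 lists and always the E2F, G2/M and replication lists. Where no gene passed, the 4 largest separated values each way were taken, and where no list member passed, the 2 largest. Genes named from single H2AZ1 hairpins were chosen after their values were seen.

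The tests were tried on simulated arrays with the real gene means and residual spreads, a hairpin correlation of 0.157, 100 genes changed by 0.5 and 100 changed by 1 on the log2 scale. For H2AZ2 the E2F list was also lowered by 0.5, and its genes counted as true changes. Each comparison rests on a single simulated data set. Noise was drawn independently for each gene, so the simulation lacks the differences between arrays that many real genes share. The shares of false calls below do not measure what such differences add. For H2AZ2 against control, with 18417 genes, 68% of the smaller and 97% of the larger changes were recovered, and 10.1% of calls were false. For H2AZ1 against control these shares were 65%, 95% and 11.1%. For sh_83 against control in the fit by hairpin they were 45%, 94% and 14.2%. The false shares exceed the threshold; the fit estimated the simulated correlation for H2AZ2 as 0.09. Calls close to the threshold, and those of single hairpins above all, are therefore less certain than their adjusted p states. Alternatives covered the block, each array and each hairpin left out, probe set averaging, a filter on the dimmest 25% of genes, centring, renormalization, the variance model and the list correlation. Figures were drawn with matplotlib 3.10.9.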

Results

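Expression was measured in SK-mel147 melanoma cells after hairpins against H2AZ1 or H2AZ2, the genes of 2 isoforms of the histone variant H2A.Z, which replaces H2A in part of the nucleosomes. The series title names proliferation and drug sensitivity as the interest of the study. The 12 arrays comprised 4 controls (2 scrambled, 2 luciferase), 4 with H2AZ2 hairpins (2 each of sh_37 and sh_38) and 4 with H2AZ1 hairpins (2 each of sh_83 and sh_84). All values are log2 expression, and n is 4 arrays per target or 2 per hairpin.

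The targeted transcripts were examined first. H2AZ2 averaged 11.00 ± 0.05 (SD, n = 4) in the controls and was lower by a log2 difference of -0.87 (SE 0.13, limma adjusted p = 0.00482) with its hairpins. It stood at 46.1% of the control level with sh_37 and at 65.4% with sh_38. H2AZ1 averaged 12.24 ± 0.12 in the controls (SD, n = 4) and was at 19.3% of that level with sh_83 (log2 difference -2.38, SE 0.09, limma adjusted p = 1.31e-06). The arrays labelled sh_84 kept H2AZ1 at 92% of the control level (log2 difference -0.12, SE 0.09, limma adjusted p = 0.859), so H2AZ1 was not measurably lower there. Over both hairpins H2AZ1 changed by -1.25 (SE 0.43, limma adjusted p = 1). For replicate 2 of these arrays the labels disagree on the hairpin. Every value for H2AZ1 knockdown below includes the arrays labelled sh_84 unless sh_83 is named alone. Neither isoform passed the test when the other was targeted: H2AZ1 changed by -0.18 (SE 0.43) with H2AZ2 hairpins and H2AZ2 by 0.03 (SE 0.13) with H2AZ1 hairpins. The SE of 0.43 carries the gap between sh_83 and sh_84, so this test could not show a modest fall of H2AZ1. For H2AZ1 all 4 arrays with H2AZ2 hairpins lay below the 4 controls. In the fit by hairpin H2AZ1 stood at -0.21 with sh_37 (SE 0.09, limma adjusted p = 0.19) and at -0.145 with sh_38 (SE 0.09, limma adjusted p = 0.396).

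**Figure D1:**
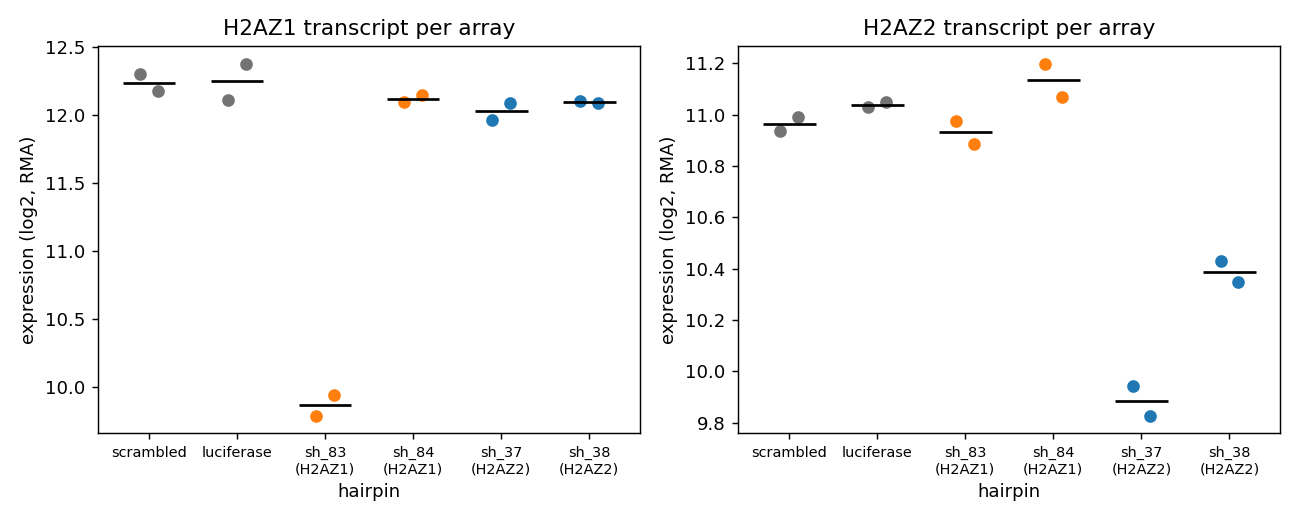
Log2 expression of H2AZ1 (left) and H2AZ2 (right) per array, by hairpin; each point is an array and each bar the mean of 2 arrays. H2AZ1 lies near 9.87 with sh_83 and near 12.12 in the arrays labelled sh_84, beside a control mean of 12.24.

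H2AZ2 knockdown against control asks which transcripts follow loss of H2A.Z.2. Among the genes that fell were many of DNA replication and the cell cycle, and among those that rose were p53 target genes. As lists these were called by camera with the preset correlation and lost with an estimated correlation (adjusted p = 0.051 for replication, 0.0579 for E2F targets, 0.0713 for G2 and mitosis and 0.051 for p53 targets). Of 18417 genes, 159 rose and 450 fell, and 193 rose and 325 fell when the arrays were quantile normalised again. EDIL3, a secreted integrin ligand, rose most by the naming rule (log2 change 2.19, SE 0.29, limma adjusted p = 0.00474, all 4 arrays above the controls). CRISPLD2 (1.69), CPA4, a carboxypeptidase (1.61), TAGLN, an actin-binding protein of contractile cells (1.53), NAT2 (1.32), DIO2, which activates thyroid hormone (1.31), DCBLD1 (1.27) and LRRC17 (1.16) followed. Several of these means rest more on sh_37 than on sh_38: TAGLN stood at 2.33 and 0.72, NAT2 at 1.94 and 0.70, DIO2 at 2.00 and 0.61 and DCBLD1 at 1.98 and 0.55. The largest falls were in MMP8, a collagenase (-1.45, SE 0.21), CEMIP2, a hyaluronidase (-1.35), ETV1, an ETS transcription factor (-1.33), IL24 (-1.29), GJA5, a gap junction protein (-1.25), ANO1, a chloride channel (-1.21), NFIB, a transcription factor (-1.17), and FST, which binds activin (-1.13). MMP8 was also lower with sh_83 (-1.10) and in the arrays labelled sh_84 (-0.73), so lower values were not particular to H2AZ2 hairpins. In the same order GJA5 stood at -1.04 and -0.105 and FST at -0.79 and 0.125, while ETV1 stood at 0.077 and 0.165.

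Genes of the replication machinery fell together after H2AZ2 knockdown. In this list 26 of 34 measured genes fell, and 34 when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 4.45e-48; adjusted p = 0.051 with an estimated correlation). POLE2, a subunit of DNA polymerase epsilon, fell by 0.93, ORC1 of the origin recognition complex by 0.78 and MCM6 of the replicative helicase by 0.73 on the log2 scale. Of 29 E2F target genes of the G1/S transition 18 fell, and 27 when adjusted over the list alone (median -0.53, camera adjusted p = 4.48e-32; adjusted p = 0.0579 with an estimated correlation). They included CDC25A, a phosphatase that activates cyclin-dependent kinases (-0.86, SE 0.22), E2F8 (-0.78) and the replication licensing factor CDC6 (-0.78). CDC25A stood at -1.33 with sh_37 and -0.40 with sh_38. E2F8 stood at -0.635 with sh_83 and 0.206 in the arrays labelled sh_84, and CDC6 at -0.556 and 0.195. Of 42 genes of G2 and mitosis 16 fell, and 39 when adjusted over the list alone (median -0.40, adjusted p = 0.0713 with an estimated correlation), among them CDK1 (-0.72), the kinetochore motor CENPE (-0.68) and ANLN, needed for cytokinesis (-0.59); in the fit by hairpin 39 fell with sh_37 and 6 with sh_38. By exact permutation of the list scores per array the E2F list gave p = 0.0286 (n = 4 per group), the smallest the design allows, and an adjusted p of 0.0615 over the 28 lists. The housekeeping list gave the same values, so this test does not set the E2F list apart, and it takes the arrays of a hairpin as exchangeable with the others. With fry, which does not compare a list with other genes, adjusted p was 0.0015 for replication, 0.00179 for E2F targets, 0.0075 for p53 targets and 0.0343 for the housekeeping list; after H2AZ1 knockdown no list passed, with 0.947 for E2F targets.

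Of 22 genes of homologous recombination and Fanconi anaemia repair 10 fell, and 18 when adjusted over the list alone (median -0.49, adjusted p = 0.0911 with an estimated correlation). XRCC2 changed by -0.85, RMI1 by -0.71 and EXO1 by -0.70. Among 21 replication-dependent histone genes 9 fell and 1 rose, against 15 and 1 adjusted over the list alone (median -0.45, adjusted p = 0.0911 with an estimated correlation), with H1-3 at -0.82, H4C4 at -0.81 and H2AC4 at -0.76. Of 21 genes that report MAPK signalling 7 fell, and 11 fell and 2 rose when adjusted over the list alone (median -0.27, adjusted p = 0.0579 with an estimated correlation). These included ETV1, SPRY4, a feedback inhibitor of the pathway (-1.12, SE 0.25), and ETV4 (-1.07). The hairpins differed here: the list median was -0.41 with sh_37 and -0.14 with sh_38 (difference -0.26, adjusted p = 0.29 with an estimated correlation), and ETV1 stood at -1.91 and -0.75.

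Of 24 p53 target genes 6 rose and none fell, and 17 rose when adjusted over the list alone (median 0.38, camera adjusted p = 1.16e-12; adjusted p = 0.051 with an estimated correlation). SESN1 changed by 0.85, the death receptor FAS by 0.67 and the cyclin-dependent kinase inhibitor CDKN1A by 0.59. In the fit by hairpin 10 rose with sh_37 (median 0.34, adjusted p = 0.052 with an estimated correlation). With sh_38 14 rose (median 0.49, adjusted p = 0.00816 with an estimated correlation). Tested directly, sh_37 minus sh_38 had a median of -0.18 (camera adjusted p = 0.00279, and 0.29 with an estimated correlation). As background, the p53 list differed between the control hairpins by a median of -0.21, scrambled minus luciferase (camera adjusted p = 3.41e-07, and 0.19 with an estimated correlation). Of 28 genes of collagens and the extracellular matrix 3 rose, and 4 when adjusted over the list alone (median 0.18, adjusted p = 0.0713 with an estimated correlation): COL4A1 (0.91), COL5A1 (0.57) and COL4A2 (0.42); in the fit by hairpin 13 rose with sh_37 and 2 with sh_38. Markers of other cell types had no called member among the keratinocyte, fibroblast, endothelial and leukocyte lists; the 12 fibroblast markers had a median of 0.20, called by camera and lost with an estimated correlation (adjusted p = 0.437). Of 23 melanocyte lineage genes 1 rose and 2 fell (median 0.01, camera adjusted p = 0.202).

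**Figure D2:**
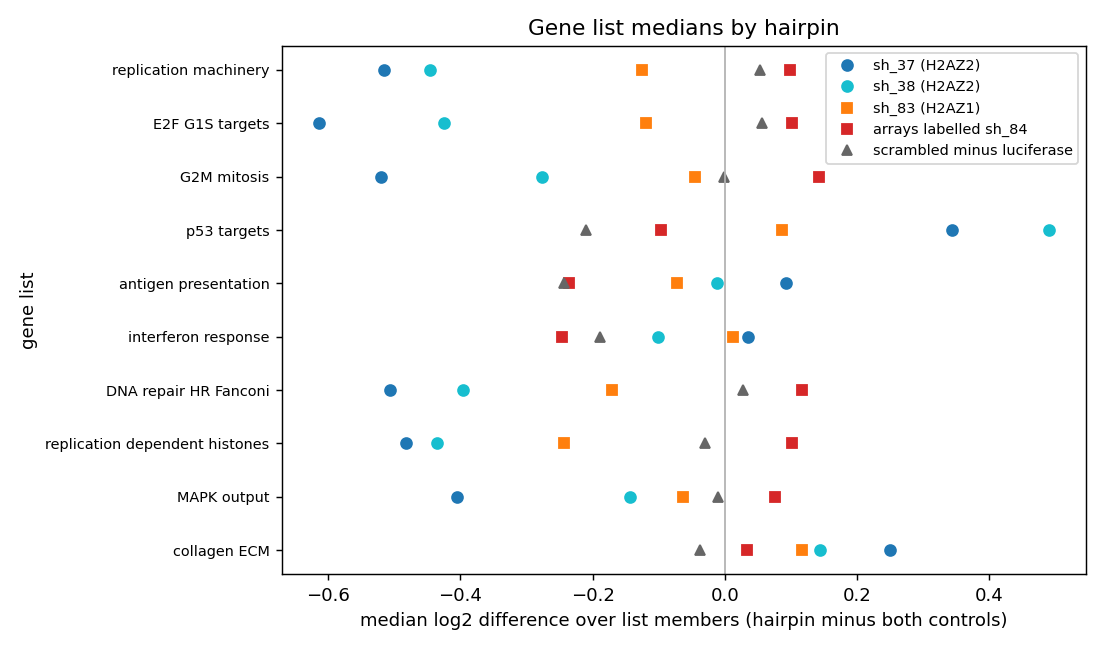
Median log2 difference of each gene list for each hairpin minus both control hairpins, with scrambled minus luciferase as background. The E2F list lies at -0.61 with sh_37 and -0.42 with sh_38, at -0.12 with sh_83 and at 0.10 in the arrays labelled sh_84.

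The count of called genes after H2AZ2 knockdown depended on single arrays: it was 609 with all arrays, 66 without replicate 1 of scrambled and 847 without its replicate 2, 329 without replicate 1 of luciferase and 235 without its replicate 2, and 302 without replicate 2 of sh_37. It was 43 without hairpin scrambled and 14 without luciferase. With the mean level of 192 small nucleolar RNAs per array as a covariate, a setting chosen after seeing the data, it was 343. Of the 18417 genes, 11.6% had non-overlapping arrays, where chance gives 2.86% for exchangeable arrays; no chance share was computed for arrays grouped by hairpin.

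Called replication genes were lower with each H2AZ2 hairpin. Against both controls in the fit by hairpin, 1053 genes rose and 1324 fell with sh_37, and 235 rose and 613 fell with sh_38. The 2 lists shared 450 genes in the same direction, 125 up and 325 down, beside 57.5 for independent lists. Simulated unchanged groups that share their controls gave a mean of 0.01, a value that leaves out the effects and so is no measure for lists of this length. With a separate control hairpin for each, 209 and 223 genes were shared, where independent lists of those sizes share 32 and 22.9. Lists from the same fit also share the estimate of spread per gene, which can bring the same genes into both without a common effect. The 450 shared genes became 77 without replicate 2 of sh_38, 204 or 191 without replicate 1 or 2 of sh_37, 280 without replicate 1 of scrambled, 213 without replicate 2 of luciferase and 294 without either replicate of sh_83, which shares in the estimate of the spread. Of 34 replication genes 31 fell with sh_37 and 26 with sh_38; the medians were -0.52 (adjusted p = 0.052 with an estimated correlation) and -0.45 (adjusted p = 0.0791 with an estimated correlation). Scrambled against luciferase gave 0 called genes with limma and 1384 at an unadjusted p under 0.05. By camera 6 of 28 lists were called between these control hairpins, beside 15 after H2AZ2 knockdown. With an estimated correlation both counts were 0.

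**Figure D3:**
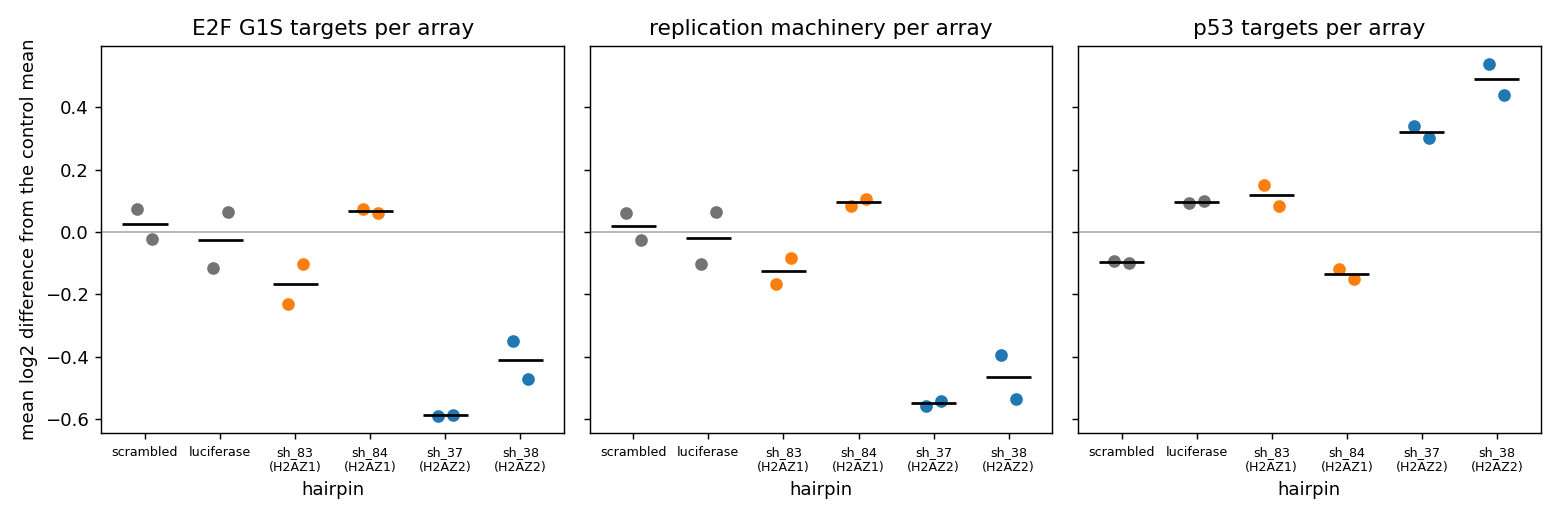
Mean log2 difference from the control mean over the members of the E2F, replication and p53 lists, per array; each point is an array and each bar the mean of 2 arrays of a hairpin. With H2AZ2 hairpins the E2F score averaged -0.50 and the p53 score 0.41.

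H2AZ1 knockdown against control asks the same of H2A.Z.1. No gene passed the limma test over the 4 arrays with H2AZ1 hairpins, which include the arrays labelled sh_84 with H2AZ1 near the control level; 636 genes had an unadjusted p under 0.05, and the fit by hairpin called 1 gene up and 6 down. Without hairpin sh_84 the count was 17. Values that did not pass, with arrays wholly apart from the controls, were highest for SEL1L3 (0.52, SE 0.23), SLC2A14 (0.42), CCR2 (0.37) and RPL23P8 (0.34) and lowest for MMP8 (-0.92, SE 0.21), HLA-DQA1, an antigen-presenting molecule (-0.86), RNF182 (-0.71) and RILPL2 (-0.70). None of 29 E2F target genes, 42 genes of G2 and mitosis or 34 replication genes passed; CCNE1 stood at -0.24, E2F8 at -0.22, TPX2 at -0.19, MAD2L1 at 0.12, GINS1 at -0.16 and POLD1 at -0.11. The E2F median was -0.02 (camera adjusted p = 0.215). It passed at -0.08 without replicate 1 of luciferase (adjusted p = 0.011), at -0.06 without replicate 1 of sh_84 (adjusted p = 0.0174) and at -0.12 without hairpin sh_84 (adjusted p = 2.99e-06), and turned to 0.10 without hairpin sh_83 (adjusted p = 0.0179); with an estimated correlation and all arrays the adjusted p was 0.94.

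Camera called 3 lists lower with H2AZ1 hairpins, without any called member. Antigen presentation had a median of -0.17 over 13 genes (adjusted p = 0.705 with an estimated correlation), with HLA-DMA at -0.42 and HLA-DPA1 at -0.41. The interferon response had a median of -0.08 over 34 genes (adjusted p = 0.775 with an estimated correlation), with SAMD9L at -0.52 and IFI6 at -0.46; it stood at 0.01 with sh_83 (camera adjusted p = 0.971) and at -0.25 in the arrays labelled sh_84 (adjusted p = 0.0929 with an estimated correlation). Cholesterol synthesis had a median of -0.09 over 18 genes (adjusted p = 0.94 with an estimated correlation), with STARD4 at -0.22 and SCD at -0.22. As background, scrambled minus luciferase gave -0.24 for antigen presentation and -0.19 for interferon response. By camera in the fit by hairpin, 6 of 28 lists were called between the control hairpins and 13 in the arrays labelled sh_84. With an estimated correlation 0 were called in either.

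With sh_83 alone, the hairpin with a measured fall of H2AZ1, 28 genes rose and 90 fell in the fit by hairpin. Against scrambled alone 23 rose and 27 fell, and against luciferase alone 12 rose and 69 fell. Genes chosen after their values were seen include SPINK1, a trypsin inhibitor (1.25, SE 0.13), GPNMB, a melanosomal glycoprotein (1.13), CELF2 (1.06), B3GALT2 (-1.39), DEGS1, a dihydroceramide desaturase (-1.10), RILPL2 (-1.06) and GJA5 (-1.04). B3GALT2 also stood at -0.86 in the arrays labelled sh_84. With H2AZ2 hairpins SPINK1 stood at 0.93, GPNMB at 0.95, B3GALT2 at -0.60 and GJA5 at -1.25. There CELF2 stood at 0.08, DEGS1 at -0.15 and RILPL2 at 0.01. By camera 4 lists were called up and 6 down with sh_83, 10 of 28, and 0 with an estimated correlation. The control hairpins gave 6 by camera against each other. The replication list had a median of -0.13 with sh_83 and no called member (camera adjusted p = 0.000167, and 0.621 with an estimated correlation). The E2F median was -0.12 and the p53 median 0.09, with 1 called member each. Camera adjusted p was 5e-06 and 0.00234, and 0.621 for both with an estimated correlation. With the arrays labelled sh_84, 2 genes rose, EDN1 (0.69) and FAT3 (0.45), and 63 fell, among them the chemokine CCL2 (-1.18), NKIRAS2 (-1.08), TLR3 (-1.01) and TRIM22 (-0.95). Against scrambled alone only NKIRAS2 was called and against luciferase alone 116 genes, so CCL2, TLR3 and TRIM22 did not pass against scrambled alone. The lists with sh_83 and sh_84 shared 3 genes, beside 0.31 for independent lists. Part of that excess may come from the shared controls and the shared estimate of spread per gene.

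H2AZ2 against H2AZ1 knockdown tests the difference directly. EDIL3 (2.65, SE 0.29), NAT2 (1.84), DACT1, an inhibitor of Wnt signalling (1.83), CRISPLD2 (1.80) and TAGLN (1.65) were higher with H2AZ2 hairpins. ETV1 (-1.45, SE 0.25), SPRY4 (-1.26), IL24 (-1.19), CEMIP2 (-1.11) and ETV5 (-1.08) were lower. Against the controls DACT1 stood at 2.61 with sh_37 and 0.62 with sh_38, SPRY4 at -1.64 and -0.60 and ETV5 at -1.53 and -0.47. EDIL3 stood at -0.03 with sh_83 and -0.895 in the arrays labelled sh_84, DACT1 at 0.27 and -0.71 and CRISPLD2 at 0.19 and -0.41. Part of these 3 differences thus lies in arrays where H2AZ1 was not measurably lower. NAT2 was lower with sh_83 (-0.78) than in the arrays labelled sh_84 (-0.26), and TAGLN stood at -0.03 and -0.21. In all 383 genes were higher and 419 lower, and the H2AZ1 arrays again include those labelled sh_84. Of the replication list 25 of 34 genes were lower (median -0.46, adjusted p = 0.0527 with an estimated correlation), including POLE2 (-0.90), ORC1 (-0.79) and MCM10 (-0.73). Of the E2F list 16 of 29 were lower (median -0.52, adjusted p = 0.0801 with an estimated correlation), including CDC25A (-0.89), WDR76 (-0.75) and CLSPN (-0.73), and of the list of G2 and mitosis 21 of 42 (adjusted p = 0.0801 with an estimated correlation), including CDK1 (-0.72), CENPE (-0.70) and ANLN (-0.67). For CDC25A the arrays of both targets overlapped.

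Of 22 repair genes 10 were lower with H2AZ2 than with H2AZ1 hairpins, including XRCC2 (-0.80), EXO1 (-0.73) and POLQ (-0.63), and of 21 histone genes 9 were lower, including H4C2 (-0.75), H2AC4 (-0.65) and H2BC9 (-0.61), and H2BC21 was higher (1.16); both lists gave an adjusted p = 0.145 with an estimated correlation. Of 24 p53 target genes 10 were higher (adjusted p = 0.0527 with an estimated correlation), with TP53INP1 at 1.56, SESN1 at 1.11 and CDKN1A at 0.73; TP53INP1 was itself lower than the controls in the arrays labelled sh_84 (-1.02). Of 18 cholesterol synthesis genes 3 were higher, HMGCS1 (0.71), INSIG1 (0.54) and MVD (0.33), with adjusted p = 0.222 with an estimated correlation; against the controls the list median was 0.22 with sh_37, with 6 genes higher, and near 0 with sh_38, with 1 higher and 2 lower. The count of 802 genes became 93 without hairpin sh_84 and 272 without replicate 1 of scrambled; leaving out replicate 1 or 2 of sh_84 gave 299 or 306, replicate 1 or 2 of sh_37 488 or 421, replicate 2 of sh_83 534 and replicate 1 of luciferase 517. Set against sh_83 alone in the fit by hairpin, 525 genes were higher and 439 lower with H2AZ2 hairpins, and the replication median was -0.34 (adjusted p = 0.133 with an estimated correlation).

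Across the 18417 genes the H2AZ2 and H2AZ1 effects correlated with r = 0.31, and genes are not independent replicates. Simulated unchanged groups that share their controls gave 0.5, a value that the shared controls fix. Effects of H2AZ2 hairpins alone lower r, so a value below 0.5 says nothing of shared effects. The covariance was 0.00768 beside a simulated 0.00734. With separate control hairpins r was -0.03 or 0.06, and both values include the arrays labelled sh_84. For sh_83 alone with separate controls, r was 0.05 and 0.29 with sh_37 and 0.25 and 0.17 with sh_38. In the same settings sh_83 and sh_37 shared 21 and 18 called genes, beside 4.11 and 2.37 for independent lists. For sh_83 and sh_38 these were 11 and 12, beside 1.21 and 0.89. The lists come from the same fit and share its estimate of spread per gene, which independent lists leave out. Sharing above those counts is therefore no measure of common effects.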

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

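The splits of the arrays, the test with small nucleolar RNA levels and the matched random lists were set out before their results were seen; the other tests in this part were chosen after the result they measure was seen, and the snoRNA covariate itself was chosen after seeing the data.

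The H2AZ1 transcript differed between its hairpins by -2.25 on the log2 scale, sh_83 minus sh_84 (limma adjusted p = 1.02e-05), with the arrays labelled sh_84 at the control level. A probe set that does not follow H2AZ1 is argued against by the difference of -2.375 with sh_83, and an exchange with other arrays of the series by 0 arrays outside sh_83 with H2AZ1 more than 1 below the control mean. Control RNA under a sh_84 label could not be decided: the fewest genes called against a single control hairpin was 1, NKIRAS2, against scrambled, with 116 against luciferase and 0 between the control hairpins, and the bound was set with these counts known. An ineffective hairpin or a sample from outside the series stays open, and the labels disagree on the hairpin of replicate 2.

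The H2AZ2 transcript differed between sh_37 and sh_38 by -0.50 (limma adjusted p = 0.00763). Between these hairpins 1155 genes and 10 gene lists differed, and between sh_83 and sh_84 219 genes and 14 gene lists, by the direct test of the hairpins. With an estimated correlation 0 of these lists passed in either comparison. Of the probe sets not listed in the annotation 22 (0.18%) were called after H2AZ2 knockdown, and of those with several symbols 31 (1.77%), beside 0 between the control hairpins. In the same fit 354 (1.82%) of those with 1 symbol were called. Among the 4 arrays with H2AZ2 hairpins, H2AZ1 was lowest in replicate 1 of sh_37, with a gap of 0.874 of the range; chance flags about 1 in 20 groups, and 9 groups were looked at.

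Cell cycle lists had lower medians with H2AZ2 hairpins, called with the preset correlation and lost with an estimated correlation (adjusted p = 0.0579 for the E2F list, 0.051 for replication and 0.0713 for G2 and mitosis). An off-target effect of a single hairpin is argued against by E2F medians of -0.64, -0.61, -0.43 and -0.375 for the hairpin and control pairs, all below -0.2. Array differences that follow small nucleolar RNA levels are argued against as the whole cause by a median of -0.493 with that covariate, which lowered the count of called genes from 609 to 343, and signal level by 0 of 10000 random lists matched on mean expression with as low a median. A difference in growth between cultures and a biological effect of H2A.Z.2 loss stay open, since the design gives no other measure of growth. A biological effect therefore stays a hypothesis.

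The antigen presentation list had a lower median with H2AZ1 hairpins, a call lost with an estimated correlation (adjusted p = 0.705). A difference between the control hairpins is consistent with a median of -0.075 against scrambled and -0.22 against luciferase, and an effect of the arrays labelled sh_84 with -0.073 for sh_83. Both explanations were tested on values already seen, so they stay candidate explanations.

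Other splits of the arrays were counted for each comparison of targets. Of the 35 splits of the 8 arrays with H2AZ2 or control hairpins, 3 gave at least the real 609 genes, the highest other 2256, so chance cannot be excluded by this count. The 2 larger splits both set replicate 1 of scrambled and sh_38 against their replicate 2, and point to a structure of the arrays: the main axis of differences within hairpins held 57.7% of that variance and lay at 0.452 and -0.452 for the scrambled arrays and 0.392 and -0.392 for sh_38. For H2AZ1 against control, all 35 splits gave 0 genes or more, the real count being 0 and the highest other 0. For H2AZ2 against H2AZ1, only the real split, 1 of 35, gave 802 genes, the highest other being 17, so chance can be excluded for single arrays taken as exchangeable. Only 3 of these splits keep the hairpins whole, with 802, 17 and 1 genes, which is too few for a share under 0.05, so this says nothing of chance between hairpins. The count was 93 without hairpin sh_84.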

How the results depend on the processing

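The snoRNA covariate and the fit without the 2 arrays lowest in snoRNA mean were chosen after seeing the data; the other settings were fixed before. Where a value moved, the cause was not tested, except that a fold threshold leaves fewer calls by construction. Genes changed by H2AZ2 knockdown numbered 609; 957 without the hairpin block, 2087 with 6 hairpins as groups, 28 with a log2 change of at least 1, 343 with the snoRNA covariate, 43 without hairpin scrambled, 14 without luciferase and 1681 without sh38, and 66 to 847 with single arrays left out. The share of falls was 73.9%, 62.1% with the covariate and 62.7% when quantile normalised again. Among genes with a log2 change of at least 1 it was 53.6%. Without the 2 arrays lowest in snoRNA mean the counts were 589 for H2AZ2, 0 for H2AZ1 and 1058 for the difference, whose share of lower genes went from 52.2% to 40.5%. Genes changed by H2AZ1 knockdown numbered 0; 2 without the block, 7 with 6 groups, 3 with trend and robust, 2 without sh83 and 17 without sh84, and 0 to 1 with single arrays left out. Genes differing between the targets numbered 802; 1211 without the block, 2364 with 6 groups, 359 with only the 8 arrays compared, 37 with a log2 change of at least 1, 446 without sh37, 1795 without sh38 and 93 without sh84, and 272 to 940 with single arrays left out. The H2AZ2 transcript fell short of the threshold without hairpin luciferase (-0.828, adjusted p = 0.0654; adjusted p 0.00414 to 0.0397 with single arrays left out, where it was -0.94 to -0.771). The H2AZ1 transcript passed with 6 groups (-1.248, adjusted p = 0.00013) and without sh84 (-2.375, adjusted p = 9.76e-07), and was -1.558 to -0.894 with single arrays left out. With an estimated correlation the called lists went from 15, 3 and 13 to 0, 0 and 0, and the E2F shift of -0.533 kept its value with adjusted p = 0.0579; with single arrays left out that shift was -0.576 to -0.494 and the lists numbered 14 to 15 for H2AZ2 and 13 to 15 for the difference. Lists changed by H2AZ1 knockdown numbered 7 without scrambled, 0 without luciferase, 13 without sh83, 10 without sh84 and 2 to 6 with single arrays left out. The E2F shift after H2AZ1 knockdown, -0.015, reversed to 0.102 without sh83, was -0.119 without sh84, and -0.08 to 0.021 with single arrays left out. The correlation of effects, 0.312, was -0.025 and 0.055 with separate controls, 0.14 with the covariate, 0.545 without scrambled, 0.171 without sh38, -0.009 without sh83, 0.469 without sh84 and 0.193 to 0.528 with single arrays left out. Genes shared by the H2AZ2 hairpins, 450, numbered 209 and 223 with separate controls and 77 to 626 with single arrays left out. Genes shared by the H2AZ1 hairpins, 3, numbered 8 with the replicate block, 7 without the dimmest 25% of genes, 15 with trend and robust, 2 and 0 with separate controls and 0 to 3 with single arrays left out. Control hairpins differed in 0 genes under every setting run. The labels give no shared batch for a replicate number, and 9 of 15 pairs of hairpins had a correlation of deviations over 0.1, not all (0.38 to 0.68 among scrambled, sh37, sh38 and sh84, down to -0.47 with luciferase), so the numbers were not taken as pairing the samples. With the replicate block H2AZ2 knockdown called 445 genes and the difference 601. Named genes kept direction in every setting where they or the alternative were called: of 1157 values for the 40 called genes of H2AZ2 against control 225 missed the threshold (35 genes without luciferase, 31 without scrambled, 23 without replicate 1 of scrambled), of 927 for the 32 called genes of the difference 109 missed it (24 genes without sh84), and of 636 for 22 genes of H2AZ1 against control 13 passed it.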

Other observations

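Gene families in this part were chosen after the data were seen. Protocadherin beta genes, a cluster of cell adhesion molecules, were higher with sh_37: 13 of 18 passed in the fit by hairpin, with a median of 0.71 (camera adjusted p = 6.04e-20; adjusted p = 0.00349 with an estimated correlation over 10 families). With sh_38 1 passed and the median was 0.11 (adjusted p = 0.353 with an estimated correlation). Over both H2AZ2 hairpins PCDHB9 (0.78, SE 0.14) and PCDHB16 (0.58, SE 0.14) rose, and the family median was 0.44 (adjusted p = 0.075 with an estimated correlation). The median was -0.25 with sh_83, -0.17 in the arrays labelled sh_84 and -0.15 for scrambled minus luciferase, with no called member in these. Against H2AZ1 knockdown 9 of 18 were higher with H2AZ2 hairpins (median 0.74, adjusted p = 0.0117 with an estimated correlation).

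Centromere protein genes had 6 members lower and 1 higher of 20 after H2AZ2 knockdown (median -0.37, adjusted p = 0.209 with an estimated correlation). CENPQ (-0.90), CENPU (-0.54) and CENPP (-0.54), which belong to the inner kinetochore, fell, and the pseudogene CENPBD2P rose (0.28). Of 39 kinesin genes 7 fell and 2 rose, and the family was not called (median -0.03, camera adjusted p = 0.131). KIF15 (-0.63), KIF11 (-0.58) and KIF4A (-0.51), motors of the mitotic spindle and chromosomes, fell, and KIF5A, a motor of axonal transport, rose (0.53). DUSP5 (-0.79), DUSP4 (-0.59) and DUSP7 (-0.32), phosphatases that act on MAP kinases, fell, of 25 genes of that family, which was not called (camera adjusted p = 0.386). CDH6, a cadherin, rose (0.99, SE 0.19; family adjusted p = 0.312 with an estimated correlation). Among 29 integrin genes, a family that was not called (camera adjusted p = 0.236), ITGA6 fell (-0.57) and ITGAV rose (0.39).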
